A study of Homo sapiens with 24 samples.

How the data were processed

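The deposited values are FPKM (fragments scaled to transcript length and library depth), computed per gene and per library by the authors, who name STAR 2.4.2a, Cufflinks 2.2.1 and the genome build hg19 without giving each program's role or settings. RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit, index Set A or B, per the labels, which do not say which set went with which library. Each of the 24 files holds 60350 genes with an FPKM, its confidence bounds and a quantification status. FPKM of rows with the same symbol were summed within a library (338 symbols stood on more than 1 row of 58266), and 74 symbols with a failed status in any library were left out. A gene was tested when its FPKM was at least 1 in at least 3 libraries, which left 15819 genes. No counts are given in the files. The effective number of fragments, gauged from the confidence bounds, ran from 8023832 to 11443293, and the depth relative to WT starved replicate 1 from 0.88 to 1.46. This sets the precision only roughly, so no counting interval is given.

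Levels were compared as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. All 24 libraries entered a single fit with a mean for each of the 8 groups (lmFit, contrasts.fit, eBayes with a trend), so that groups of 3 share an estimate of the spread. The adding of 1 shrinks changes of genes near 0. Tests were two-sided, with Benjamini-Hochberg adjusted p over all genes tested, and a gene was called at an adjusted p under 0.05. Of 17 comparisons, 6 set a knockout against WT, 4 set LPA against starved cells, 3 are interactions (LPA response of a knockout minus that of WT), 3 set a knockout against a knockout in starved cells, and 1 tests non-additivity (dKO minus the sum of the single knockouts, in starved cells). A list test used camera with a preset correlation of 0.01 and, beside it, an estimated correlation, both adjusted over the 26 lists; fry was run too. The levels of YAP1 and WWTR1 over both conditions were compared by exact permutation of 6 against 6 libraries. Replicate numbers were not treated as pairs: across 28 pairs of groups, 0 had a correlation over 0.1 for every replicate number.

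The 26 gene lists, the tests, the rule for naming genes and a first set of other settings were written before the data were examined. The lists hold YAP/TAZ conserved targets, Hippo pathway components, immediate-early genes, SRF/MRTF cytoskeletal targets, LPA receptors and LPA metabolism, extracellular matrix, cell adhesion and focal adhesion, G1/S and DNA replication, G2/M and mitosis, glycolysis and glucose uptake, hypoxia targets, cholesterol synthesis, amino acid and unfolded protein stress, p53 targets, NF-kB and inflammatory mediators, interferon-stimulated genes, TGF-beta targets, Wnt/beta-catenin targets, Notch targets, epithelial markers, mesenchymal and smooth muscle markers, neuronal and neuroendocrine markers, cytosolic ribosomal proteins, ribosome biogenesis, nuclear-encoded oxidative phosphorylation, and replication-dependent histones as a sign of RNA selection. A comparison may name YAP1 and WWTR1, the 8 largest increases and the 8 largest decreases among called genes whose groups do not overlap (not required for interactions) and whose higher group has a mean FPKM of at least 2, up to 4 called members of each list described by size of change, and CTGF, CYR61, ANKRD1, FOS, EGR1 and MYC whatever their result. A gene named once may be followed elsewhere. Names are taken from the top of each order. Skipping clone names, read-through transcripts and pseudogenes that met the rule was decided after their values were seen. Genes whose FPKM was near 0 in some genotypes, and those in the chromosome segments, were also named after their values were seen.

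Because the libraries differed in GC trend, a GC correction was added after seeing the data: each library's log2 deviation from the mean library was fitted by loess (span 0.3) on transcript GC content, over genes with a mean FPKM of at least 5, and subtracted. GC content was that of the longest GENCODE v29 transcript with the same Ensembl gene ID, found for 15554 of the genes tested (98.3%). A library counts as shifted when the mean of its fitted curve over the top decile of genes by GC content lay below -1 log2 units. The fit was tested on simulated data with 200 changed genes. Without a GC trend it recovered 92.5% of 2-fold changes with 11 false calls. With the trend of the real libraries the TAZ_KO comparison made 12270 false calls uncorrected and 10 corrected, when 92.5% of 2-fold changes were recovered. The simulated trend was the curve fitted by this same correction, with noise taken from the WT starved libraries, so its removal was built in. These counts do not show how well the correction works on the real shifted libraries.

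Other settings chosen beforehand were pseudocounts of 0.1 and 0.5, no FPKM filter, a filter at FPKM 5, TPM rescaling, trimmed-mean scaling, quantile normalization, a replicate block, a robust eBayes, library quality weights, only the groups compared in the fit, a fold of at least 1.5 besides the adjusted p, and leaving out each library in turn. Settings added after seeing the data were the GC correction (also with only the groups compared, and with only genes of GC content under 0.48), leaving out the 8 shifted libraries, leaving out libraries for the deleted genes, and list tests without the genes of chromosome 3 from 90 Mb and of chromosome 5 from 50 to 90 Mb. For each gene test, groups were also split in other ways with a fixed seed, up to 100 splits. Raw reads were not used here.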

Results

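RNA was sequenced from HEK293A cells, a human embryonic kidney cell line, of 4 genotypes: wild type (WT), knockout of YAP (YAP_KO), knockout of TAZ (TAZ_KO) and knockout of both (dKO). YAP, encoded by YAP1, and TAZ, encoded by WWTR1, are transcriptional coactivators held in check by the Hippo pathway. Cells of each genotype were collected after 16 h without serum (starved), or after starvation followed by 90 min with 100 nM lysophosphatidic acid (LPA), a serum lipid that signals through G protein-coupled receptors. Each of the 8 groups held 3 biological replicates, which gave 24 libraries. The purpose stated for the series was to compare expression at the starved baseline and the response to LPA between the genotypes. How many independent clones stood behind a genotype, and whether a vehicle was added to the starved cells, are not given in the sources used here. The effective depth read from the files' own confidence bounds ran from 8023832 to 11443293 fragments per library, and 12123 to 14451 genes reached an FPKM of 1 (fragments scaled to transcript length and library depth). Changes below are differences in log2(FPKM + 1) with the standard error (SE) of the limma fit, and levels are mean FPKM ± SD over n = 3 libraries unless another n is given.

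The libraries differed in how the level of a gene followed its GC content. The first principal component of the 15819 genes tested held 67.7% of the variance, and across genes its loadings had a Spearman correlation of -0.80 with GC content (genes are not independent replicates). In 8 libraries, all 6 of TAZ_KO and replicates 1 and 2 of YAP_KO with LPA, the decile of genes with the highest GC content sat between -4.56 and -1.56 log2 units from the mean of all libraries, by the mean of the library's fitted GC curve. In the other 16 libraries the same genes sat between 0.0574 and 0.80. Values from a fit on levels corrected for GC content, and counts without these 8 libraries, were chosen after seeing the data and are given beside the comparisons. After the correction the first component still held 44.2% of the variance and set the same 8 libraries apart, so it did not remove every difference between them and the others.

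The deleted genes kept part of their mRNA. YAP1 stood at 10.5 ± 1.30 FPKM (n = 6 libraries, both conditions together) in YAP_KO and 6.16 ± 0.780 in dKO against 32.9 ± 1.97 in WT, that is 31.9% and 18.8% of WT. WWTR1 stood at 24.2 ± 2.46 FPKM in TAZ_KO and 16.3 ± 0.725 in dKO against 48.5 ± 5.90 in WT, that is 49.8% and 33.7%. Each of these 4 differences had a two-sided exact permutation p of 0.00216, the smallest that 6 against 6 libraries allow. YAP1 was at 135% of WT in TAZ_KO (same exact permutation p), a difference that was 0.0600 in log2 in starved cells after GC correction (adjusted p = 0.537) against 0.49 before. WWTR1 in YAP_KO, at 52.4 ± 3.14 FPKM, did not differ from WT by the exact permutation test (p = 0.182), except without WT LPA replicate 2, when it was at 112% of WT. In hg19 the files place YAP1 (ENSG00000137693.13, chromosome 11, 101981192 to 102104154) and WWTR1 (ENSG00000018408.14, chromosome 3, 149235022 to 149454501), so WWTR1 lies in the part of chromosome 3 described below. A transcript level does not show whether protein is made.

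**Figure D1:**
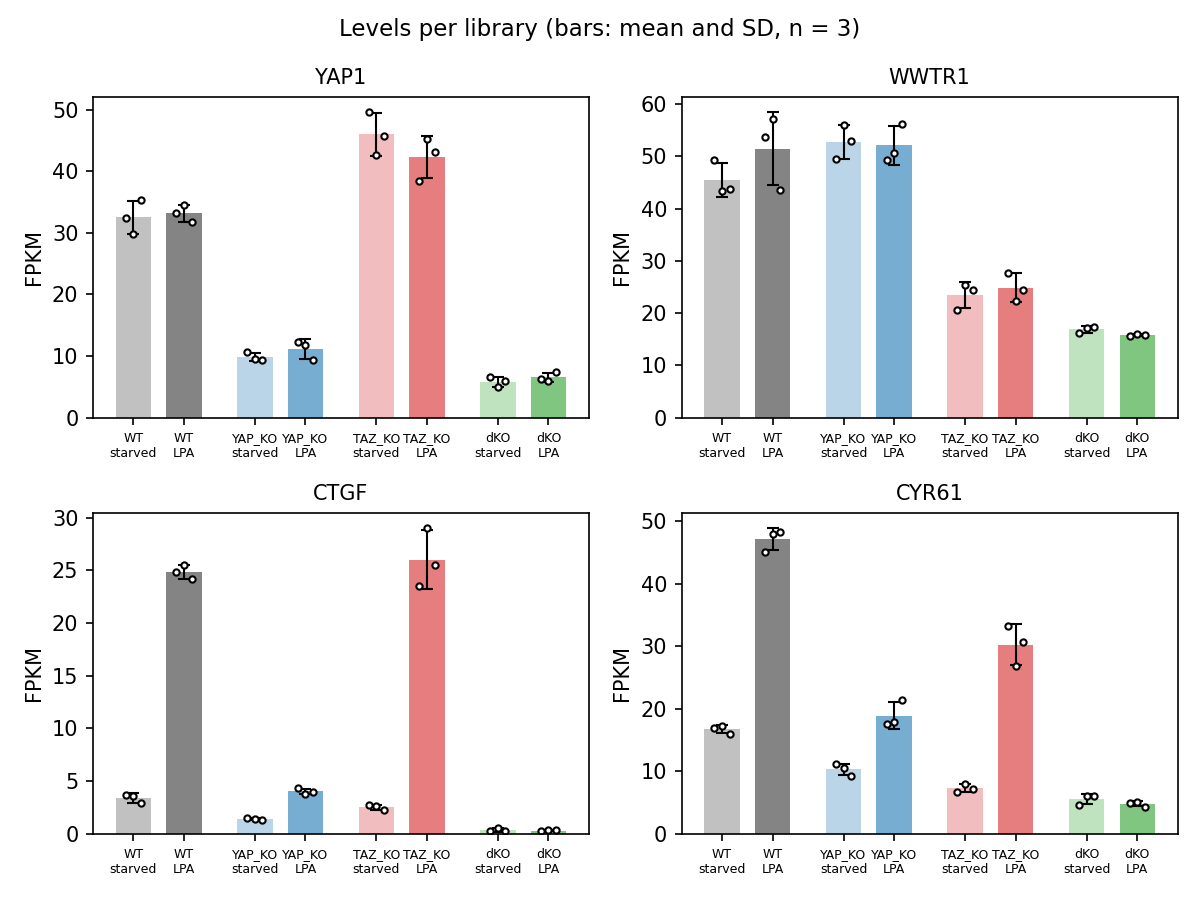
FPKM of YAP1, WWTR1, CTGF and CYR61 in each of the 24 libraries (points), by genotype and condition, with the group mean (bar) and its SD (n = 3). In dKO the mean CTGF level was 0.377 ± 0.161 FPKM starved and 0.306 ± 0.0295 with LPA, against 3.39 ± 0.440 and 24.8 ± 0.632 in WT.

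Loss of YAP in starved cells came with lower CTGF and CYR61, the classic secreted-factor targets of YAP and TAZ, and with larger changes in cyclin, transporter and keratin genes. CTGF fell by 0.88 log2 units (SE 0.10, adjusted p = 3.0e-06) from 3.39 ± 0.440 to 1.38 ± 0.107 FPKM, and CYR61 fell by 0.65 (adjusted p = 1.8e-04). CCND1, the G1 cyclin D1, rose by 3.53 ± 0.21 from 5.61 ± 1.02 to 74.7 ± 3.60 FPKM, and LGR5, an R-spondin receptor, by 3.28 ± 0.13. SLC7A5, which carries large neutral amino acids into cells, had a change of -5.20 ± 0.40, and KRT19, an epithelial keratin, of -3.53 ± 0.33. Among 3653 genes called by limma at an adjusted p under 0.05, 2191 were higher and 1462 lower in YAP_KO.

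The genes with the largest increases in YAP_KO were PUDP, CCND1, FLRT2, B3GNT8, TRIB2, LGR5, RFX7 and TEX9, between 3.11 and 3.60. PUDP, RFX7 and TEX9 were near 0 in WT (0.0106 ± 0.00921, 0.000980 ± 0.00170 and 0.00556 ± 0.00963 FPKM) and stood at 11.2 ± 0.384, 8.64 ± 0.315 and 7.73 ± 0.865 in YAP_KO. FLRT2, a cell-surface guidance protein, and TRIB2, a pseudokinase, rose by 3.42 ± 0.15 and 3.29 ± 0.0760. B3GNT8, a glycosyltransferase, rose by 3.34 ± 0.90 (adjusted p = 0.0117), a call lost without YAP_KO starved replicate 3 (adjusted p = 0.0537) and after GC correction (adjusted p = 0.0501). After SLC7A5 and KRT19, the largest named decrease was that of VAMP8, a vesicle-fusion protein (-2.97 ± 0.25). ANKRD1, another target of YAP, was lower (-0.60, adjusted p = 2.4e-05) and MYC higher (0.64, adjusted p = 0.0140). FOS (0.49, adjusted p = 0.0776) and EGR1 (-0.22, adjusted p = 0.210) did not pass the test, although library quality weights gave 0.020 for FOS and 0.0423 for EGR1, FOS had an adjusted p of 0.0221 without YAP_KO starved replicate 3, and EGR1 of 0.0452 when the fit held only the groups compared.

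By gene group, the amino acid and unfolded protein stress genes fell in YAP_KO: 2 of 26 tested were higher and 11 lower (2 and 11 adjusted over the list alone), with camera adjusted p = 1.3e-04 and adjusted p = 0.0347 with an estimated correlation. SLC3A2, the partner chain of SLC7A5, had a change of -2.19 ± 0.23 and TRIB3, a stress-induced pseudokinase, of -0.85 ± 0.25 (adjusted p 0.0649 without WT starved replicate 2 and 0.0574 without YAP_KO starved replicate 3). Wnt/beta-catenin targets rose: 7 of 14 tested were higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00711, a call lost at adjusted p = 0.255 with an estimated correlation. They included APCDD1, a Wnt inhibitor (0.88), besides CCND1 and LGR5. Epithelial markers fell, among them KRT8 (-2.06). Of 11 tested, 1 was higher and 5 lower (1 and 7 adjusted over the list alone), with camera adjusted p = 0.00256, lost at adjusted p = 0.236 with an estimated correlation. Mesenchymal markers rose, with SNAI2 and ZEB2, transcription factors of epithelial-mesenchymal transition, at 1.73 and 0.95, and the set p was 0.0686 after GC correction and 0.10 with quantile normalization. Of 15 tested, 6 were higher and 0 lower (6 and 0 adjusted over the list alone), with camera adjusted p = 0.0362, lost at adjusted p = 0.255 with an estimated correlation.

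Metabolic and translation genes fell as groups in YAP_KO, each with a preset correlation only. For cholesterol synthesis, 1 of 24 tested was higher and 5 lower (1 and 5 adjusted over the list alone), camera adjusted p = 0.00418; adjusted p = 0.255 with an estimated correlation. Members include IDI1, an isoprenoid isomerase, at -0.97 and SQLE, squalene epoxidase, going the other way at 0.99. For glycolysis and glucose uptake, 1 of 28 tested was higher and 4 lower (1 and 4 adjusted over the list alone), camera adjusted p = 0.00878; adjusted p = 0.430 with an estimated correlation. Members include the glucose transporter SLC2A3 at -1.38 and LDHA at -0.72. For nuclear-encoded oxidative phosphorylation, 0 of 35 tested were higher and 13 lower (0 and 14 adjusted over the list alone), camera adjusted p = 2.5e-04; adjusted p = 0.318 with an estimated correlation, led by NDUFS1 at -0.65 and NDUFA9 at -0.53. For ribosome biogenesis, 0 of 25 tested were higher and 5 lower (0 and 7 adjusted over the list alone), camera adjusted p = 4.3e-04; adjusted p = 0.318 with an estimated correlation. For cytosolic ribosomal proteins, 0 of 48 tested were higher and 5 lower (0 and 5 adjusted over the list alone), camera adjusted p = 0.00256; adjusted p = 0.687 with an estimated correlation. Quantile normalization also ended the calls of glycolysis (adjusted p = 0.0564) and cytosolic ribosomal proteins (0.256). UTP15 (-1.14) and RPS23 (-0.89) lie on chromosome 5 between 50 and 90 Mb. In that segment 96 of 153 tested genes were lower in YAP_KO (62.7%, median -0.55), against 8.72% of genes outside this segment and the distal part of chromosome 3. Without the genes of both segments the list calls named for YAP_KO were kept, for example amino acid stress at an adjusted p of 7.5e-05 and ribosome biogenesis at 0.00128.

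The list of conserved YAP/TAZ targets did not move one way in YAP_KO: 3 of 17 tested were higher and 5 lower (3 and 5 adjusted over the list alone), camera adjusted p = 0.353, with FOXF2, a forkhead factor (1.29), and DOCK5 (0.95) higher beside the lower CTGF and CYR61. Immediate-early genes went both ways, with FOSL1 at -1.23 and TRIB1 at 1.19. Of 42 tested, 9 were higher and 6 lower (10 and 8 adjusted over the list alone), with camera adjusted p = 0.661. For extracellular matrix genes, 13 of 39 tested were higher and 5 lower (15 and 5 adjusted over the list alone) and the set did not pass the test (camera adjusted p = 0.0511, 0.0185 after GC correction and 0.0499 with a pseudocount of 0.1), with CD44, a hyaluronan receptor, at 1.40 and NID2, a basement-membrane protein, at 1.30. Replication-dependent histones, whose transcripts mostly lack poly(A) tails and so can reflect RNA selection, were higher as a set. Of 18 tested, 7 were higher and 2 lower (10 and 2 adjusted over the list alone), with camera adjusted p = 0.0381, lost at adjusted p = 0.323 with an estimated correlation. With quantile normalization the histone set had an adjusted p of 0.111, and of 0.0508 with a replicate block. HIST1H2AC was at 1.41 and HIST1H1C at 1.77 (adjusted p 0.0523 without WT starved replicate 2, 0.0506 without YAP_KO starved replicate 1 and 0.0501 without YAP_KO starved replicate 2). The count of 3653 genes was 5326 after GC correction and 6822 without the 8 libraries.

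Loss of TAZ in starved cells came with lower CYR61 and with FLRT2, LGR5, SLC7A5 and KRT19 moving as they did without YAP, on top of a GC-linked difference that touched most genes. CYR61 fell by 1.1 log2 units (SE 0.11, adjusted p = 1.2e-06), and its change was -0.86 after GC correction. FLRT2 rose by 3.32 ± 0.15 (2.80 after GC correction) and LGR5 by 2.66 ± 0.13 (2.29). SLC7A5 had a change of -5.66 ± 0.40 (-2.73 after GC correction) and KRT19 of -3.37 ± 0.33 (-1.33). CTGF was at -0.31 (adjusted p = 0.00780) and at 0.0299 after GC correction (adjusted p = 0.885), so its direction turned, as it did with quantile normalization. Its call was also lost with TPM rescaling (adjusted p = 0.216), trimmed-mean scaling (0.135) and only the groups compared (0.0518). limma called 11950 genes, 5536 higher and 6414 lower in TAZ_KO.

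The largest named decreases in TAZ_KO were in ATP5D, MIF, NDUFB7, TCEB2 and FASN, genes of the respiratory chain, cytokine signalling, elongin and fatty acid synthesis. Their changes lay between -6.81 and -6.47, and between -3.74 and -2.24 after GC correction, with MIF at 7.89 ± 2.59 FPKM against 940.0 ± 336 in WT. Calls that GC correction ended included those of CCNF, cyclin F (-2.02 to -0.12, adjusted p = 0.466), AMOTL2, an angiomotin of the Hippo pathway (-1.56 to -0.15, adjusted p = 0.351), MYC (-1.27 to -0.25, adjusted p = 0.136) and JUNB (-2.09 to -0.48, adjusted p = 0.246). It turned EGR1 (-0.45 to 0.19). ANKRD1 (0.0538, adjusted p = 0.550) and FOS (-0.18, adjusted p = 0.409) did not pass the test, and ANKRD1 did after quantile normalization (adjusted p = 1.9e-04).

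By gene group in TAZ_KO, for conserved YAP/TAZ targets 4 of 17 tested were higher and 8 lower (4 and 8 adjusted over the list alone) and camera gave an adjusted p of 0.759. For cytosolic ribosomal proteins 6 of 48 tested were higher and 32 lower (6 and 32 adjusted over the list alone), a set decrease (camera adjusted p = 0.0225, 2.5e-04 after GC correction, lost at adjusted p = 0.853 with an estimated correlation), with RPS15 at -5.85 and RPS9 at -4.90. SRF/MRTF cytoskeletal targets fell too, with the actin-binding FLNA at -4.57 (-1.48 corrected) and PDLIM7 at -3.80 (-1.34). Of 25 tested, 3 were higher and 18 lower (3 and 18 adjusted over the list alone), with camera adjusted p = 0.0225, 0.198 after GC correction, adjusted p = 0.808 with an estimated correlation. G2/M and mitosis genes rose as a set, while AURKB, a mitotic kinase, and CCNF were lower (-2.33 and -2.02; -0.86 and -0.12 corrected). Of 34 tested, 21 were higher and 8 lower (22 and 8 adjusted over the list alone), with camera adjusted p = 0.0225, 0.132 after GC correction, adjusted p = 0.808 with an estimated correlation. Among immediate-early genes, NR4A1, a nuclear receptor, was at -2.53 and at -1.44 after correction. For immediate-early genes 7 of 42 tested were higher and 24 lower (7 and 24 adjusted over the list alone), camera adjusted p = 0.0856, and the sets below did not pass the test either. For NF-kB and inflammatory mediators 2 of 10 tested were higher and 7 lower (2 and 7 adjusted over the list alone), camera adjusted p = 0.315, and for hypoxia targets 7 of 20 tested were higher and 11 lower (7 and 11 adjusted over the list alone), camera adjusted p = 0.759. For TGF-beta targets 3 of 14 tested were higher and 11 lower (3 and 11 adjusted over the list alone), camera adjusted p = 0.278, and for Notch targets 2 of 11 tested were higher and 7 lower (2 and 7 adjusted over the list alone), camera adjusted p = 0.278.

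Across genes, the log2 change in TAZ_KO had a Spearman correlation of -0.79 with GC content, and of -0.0301 after GC correction, when 8926 genes were called. Of 11824 calls that could be tested again, 5934 were called in the same direction and 1589 in the opposite one, and quantile normalization moved the median of all genes from -0.0830 to 0.35.

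With both YAP and TAZ deleted, starved cells had lower CTGF and CYR61 than with YAP deleted alone, less SLC7A5, KRT19 and BST2 mRNA than WT, and more NEFL mRNA. CTGF fell by 1.68 log2 units (SE 0.10, adjusted p = 4.0e-10) from 3.39 ± 0.440 to 0.377 ± 0.161 FPKM, and CYR61 fell by 1.44 (adjusted p = 9.5e-09). NEFL, the neurofilament light chain, rose by 5.27 ± 0.10 from 13.4 ± 0.283 to 559.9 ± 80.3 FPKM. SLC7A5 had a change of -4.44 ± 0.40, KRT19 of -4.00 ± 0.33, and BST2, the antiviral tetherin, of -3.66 ± 0.37. limma called 4205 genes, 2189 higher and 2016 lower in dKO.

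After NEFL, the largest increases were those of CCND1 (3.85), PUDP, TRIB2, LGR5, CTNNA3, an alpha-catenin, RFX7 and FLRT2, down to 3.16. After SLC7A5 and KRT19, the named decreases were those of TAF7L, a transcription initiation factor (-3.78 ± 0.11), BST2, and AP1M2, a clathrin adaptor of polarised cells (-3.60 ± 0.32). PUDP, TRIB2, LGR5, CTNNA3 and RFX7 stood at 3.58, 3.46, 3.46, 3.42 and 3.22. ANKRD1 was lower (-0.80, adjusted p = 5.6e-07), MYC higher (0.85, adjusted p = 0.00133), and FOS did not pass the test (0.16, adjusted p = 0.610). EGR1 was lower by limma (-0.35, adjusted p = 0.0345), a call lost after GC correction (adjusted p = 0.120), with no FPKM filter (0.0747), quantile normalization (0.0892) or a replicate block (0.0516), and without single libraries (adjusted p 0.131 without dKO starved replicate 1, 0.0630 without dKO starved replicate 2, 0.0907 without WT starved replicate 1, 0.0786 without WT starved replicate 2 and 0.0685 without WT starved replicate 3).

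Genes of a long stretch of chromosome 3 were lower in dKO. Of 457 tested genes from 90 Mb to its end, 300 were lower in dKO (65.6%, median -0.68), against 10.7% of genes outside both segments, and 93 of 153 genes of the chromosome 5 segment were lower too (60.8%, median -0.52). WWTR1 itself, CCDC80, AMOTL2 and ECT2 lie in the chromosome 3 stretch, and ITGA1 and CCNB1 in the chromosome 5 segment. These limits of the segments were chosen after seeing the data. They are the longest runs and not the only low stretches: of 275 bins of 10 Mb, 29 had a median below -0.3 in dKO, including bins of chromosomes 7, 9, 11, 12 and 14. In YAP_KO 12 had, including bins of chromosomes 12 and 16 and of chromosome 5 beyond 90 Mb. On chromosome 14 from 60 to 70 Mb, for example, the median was -0.40 in dKO and 0.10 in YAP_KO.

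**Figure D2:**
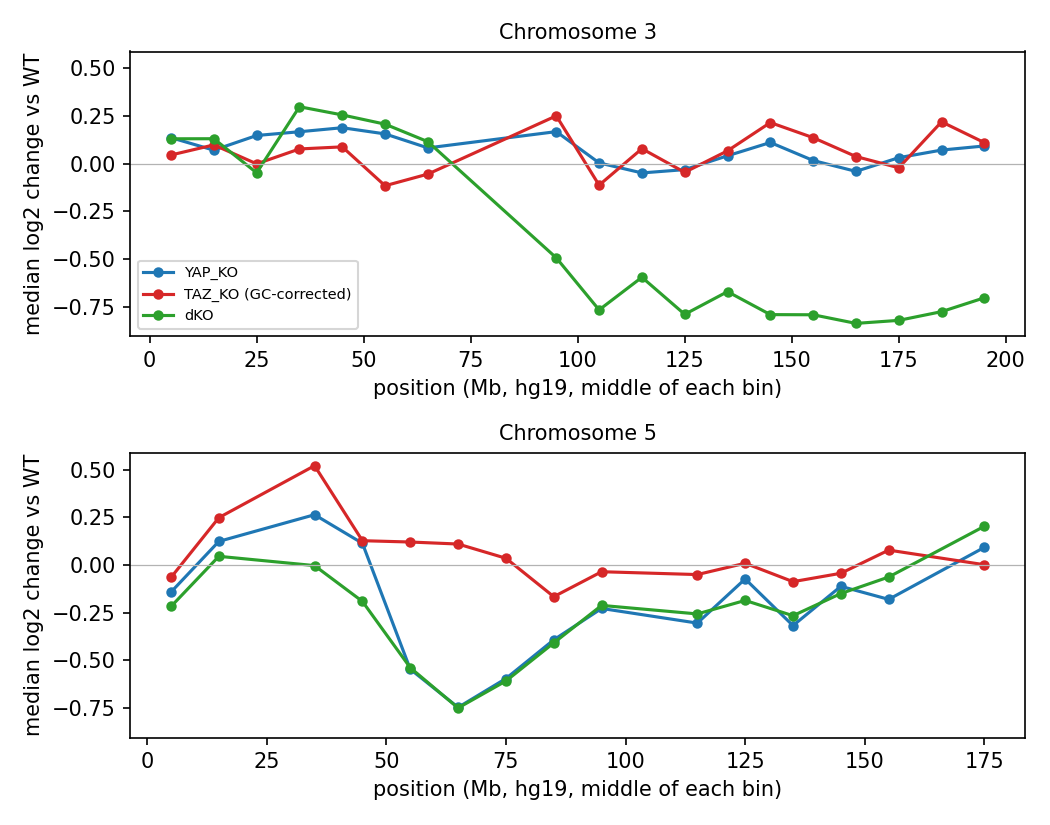
Median log2 change of tested genes in starved cells (vertical axis) in bins of 10 Mb along chromosomes 3 and 5 (horizontal axis, Mb, hg19) for YAP_KO, TAZ_KO (GC-corrected) and dKO against WT. In dKO the bins of chromosome 3 from 90 Mb on lie between -0.84 and -0.49, and in YAP_KO those of chromosome 5 from 50 to 90 Mb between -0.75 and -0.39.

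Conserved YAP/TAZ targets fell as a set in dKO: 3 of 17 tested were higher and 8 lower (4 and 9 adjusted over the list alone), camera adjusted p = 0.0446, and adjusted p = 0.170 with an estimated correlation. CCDC80, an extracellular matrix protein, was at -2.45 ± 0.15 and FOXF2 went the other way at 1.38; without the genes of both segments the set had an adjusted p of 0.137. Among Hippo pathway components 4 of 35 tested were higher and 4 lower (4 and 4 adjusted over the list alone), camera adjusted p = 0.312, with AMOTL2 at -1.36 and AMOT, its relative on the X chromosome, at 0.91. Cholesterol synthesis genes fell, with IDI1 at -1.57. Of 24 tested, 1 was higher and 10 lower (1 and 10 adjusted over the list alone), with camera adjusted p = 0.00201, 0.00133 without the segments, lost at adjusted p = 0.170 with an estimated correlation. Interferon-stimulated genes fell, with IFITM3, which blocks viral entry, at -2.92 and OAS3, an antiviral synthetase, at -1.87. Of 24 tested, 2 were higher and 8 lower (2 and 8 adjusted over the list alone), with camera adjusted p = 0.00992, 0.00376 without the segments, lost at adjusted p = 0.170 with an estimated correlation. Wnt/beta-catenin targets rose, with AXIN2, a feedback inhibitor, at 0.92. Of 14 tested, 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 0.00713, 0.00609 without the segments, lost at adjusted p = 0.170 with an estimated correlation. Epithelial markers fell, with KRT8 at -1.72. Of 11 tested, 2 were higher and 6 lower (2 and 7 adjusted over the list alone), with camera adjusted p = 0.0309, 0.137 without the segments, lost at adjusted p = 0.223 with an estimated correlation.

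Other lists in dKO held changed members without passing the set test. Among LPA receptors and LPA metabolism genes 4 of 17 tested were higher and 4 lower (4 and 5 adjusted over the list alone), camera adjusted p = 0.984; median -0.0391, mean 0.10, with ENPP2, the enzyme autotaxin that makes LPA, at 2.65 ± 0.10 and LPAR6, an LPA receptor, at 1.31 ± 0.11. For extracellular matrix 10 of 39 tested were higher and 8 lower (11 and 8 adjusted over the list alone), camera adjusted p = 0.984, direction up; median 0.0777, mean -0.0059. Members include SPARC, a matricellular protein, at -3.51 ± 0.22 and LAMA4, a laminin chain, at -2.24. For cell adhesion and focal adhesion 3 of 30 tested were higher and 8 lower (3 and 8 adjusted over the list alone), camera adjusted p = 0.149. Members include CAV1, caveolin 1, at -1.31 and the integrin ITGA1 at -0.74. For G1/S and DNA replication 12 of 41 tested were higher and 4 lower (13 and 4 adjusted over the list alone), camera adjusted p = 0.149, and for G2/M and mitosis 1 of 34 tested was higher and 12 lower (1 and 12 adjusted over the list alone), camera adjusted p = 0.0510, 0.0253 after GC correction, with CCNB1, cyclin B1, at -0.92 and ECT2 at -0.90. For p53 targets 2 of 21 tested were higher and 5 lower (2 and 6 adjusted over the list alone), camera adjusted p = 0.0948. Members include DDB2, a DNA repair factor, at -1.56 and TP53I3 at -1.21. For neuronal markers 3 of 15 tested were higher and 4 lower (3 and 6 adjusted over the list alone), camera adjusted p = 0.984, direction up; median -0.0545, mean 0.32. Members include SOX11 at 2.05 besides NEFL. HEY1, a Notch target, was at 1.18 in a list with 2 of 11 higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.305). The count of 4205 genes was 7196 without the 8 libraries of shifted GC trend.

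With TAZ deleted on top of YAP, CTGF and CYR61 were lower than with YAP deleted alone. From YAP_KO to dKO in starved cells CTGF fell by 0.80 (SE 0.10, adjusted p = 2.2e-05) and CYR61 by 0.79 (adjusted p = 5.3e-05). YAP1 (-0.67) and WWTR1 (-1.59) were lower too. NEFL (4.10), ENPP2 (2.30), UNCX, a homeobox factor (1.84), and PLPP2, a lipid phosphatase that degrades LPA (1.83), had the largest named increases. B3GALNT1 (-2.90) and TRIM59 (-2.81), both on the low part of chromosome 3, OAS3 (-2.72), ERAP2, an antigen-trimming peptidase (-2.57), and SPARC (-2.57) had the largest named decreases. limma called 1700 genes, 509 higher and 1191 lower in dKO, and 3046 after GC correction or 4179 without the 8 libraries.

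Conserved YAP/TAZ targets fell as a set from YAP_KO to dKO. Of 17 tested, 0 were higher and 5 lower (0 and 6 adjusted over the list alone), with camera adjusted p = 0.00208, adjusted p = 0.0253 with an estimated correlation. The estimated correlation gave 0.0876 after GC correction, and without the chromosome segments the adjusted p was 0.010 or, with an estimated correlation, 0.0571. CCDC80 (-1.84) and AMOTL2 (-0.97), both on chromosome 3, led the list. Amino acid and unfolded protein stress genes rose, with the cystine transporter SLC7A11 at 0.71 and XBP1 at 0.57. Of 26 tested, 4 were higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 1.8e-04, adjusted p = 0.0253 with an estimated correlation. The SLC7A11 call was lost under quantile normalization (adjusted p = 0.0624). Cell adhesion genes fell, with the integrin ITGB5, of chromosome 3, at -1.11 and FERMT2 at -0.59 (adjusted p 0.0570 without YAP_KO starved replicate 3). Of 30 tested, 0 were higher and 7 lower (0 and 7 adjusted over the list alone), with camera adjusted p = 0.00517, adjusted p = 0.0339 with an estimated correlation. Without the segments, the estimated correlation gave 0.0571 for cell adhesion and 0.0505 for amino acid stress, so both calls were lost there. Ribosome biogenesis genes rose, with RRS1 at 0.75 (adjusted p = 0.0696 after GC correction) and RRP1B at 0.50. Of 25 tested, 4 were higher and 0 lower (5 and 0 adjusted over the list alone), with camera adjusted p = 7.8e-07, lost at adjusted p = 0.119 with an estimated correlation. Replication-dependent histones, listed as a possible sign of RNA selection, fell in this comparison as well, with HIST1H2BD at -0.94 and HIST1H2AC at -0.65 (adjusted p = 0.0665 with quantile normalization). Of 18 tested, 0 were higher and 5 lower (0 and 6 adjusted over the list alone), with camera adjusted p = 0.00208, lost at adjusted p = 0.119 with an estimated correlation. A difference in RNA selection between these libraries is therefore not excluded for the sets above.

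Comparisons with TAZ_KO carried the GC-linked difference. CTGF was lower in YAP_KO than in TAZ_KO (-0.56, adjusted p = 5.9e-05; -0.91 after GC correction), while CYR61 was higher (0.45, adjusted p = 9.9e-04; 0.18 with adjusted p = 0.0977 after GC correction), and quantile normalization turned its direction. YAP1 differed by -2.12 and WWTR1 by 1.14, and the largest changes were in TCEB2 (6.32; 3.49 corrected) and NDUFB7 (5.95; 2.72), with VAMP8 among the lower genes (-2.44). In dKO against TAZ_KO, CTGF was at -1.36 (adjusted p = 4.3e-09), CYR61 at -0.34 (adjusted p = 0.00747; 0.0573 without dKO starved replicate 1 and 0.0634 with only the groups compared in the fit), and YAP1 at -2.79. WWTR1 was at -0.45 there and at 0.13 after GC correction (adjusted p = 0.483). TAF7L (-4.19) and TRIM59 (-3.49) were lower, and MIF (6.31; 1.92 corrected) and FASN (6.16; 2.39) higher. limma called 11649 genes in YAP_KO against TAZ_KO (6763 higher, 4886 lower) and 11828 in dKO against TAZ_KO (6632 higher, 5196 lower). After GC correction these were 9332 and 9862. In the first, of 11527 calls tested again, 6265 were called the same way and 1493 the opposite way. In the second, of 11701 these were 6561 and 1656. Quantile normalization moved the median of all genes from 0.16 to -0.31 in the first and from 0.12 to -0.30 in the second.

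The changes of YAP_KO and TAZ_KO against WT overlapped in part. Of 2679 genes called in both, 1713 went the same way (1151 higher, 562 lower) and 966 opposite ways, where independence would give 767 higher and 593 lower in both. Both comparisons share the WT libraries, and the correlation of log2 changes across genes was 0.24, against 0.49 in simulations with the shared WT libraries alone. The covariance, to which shared libraries add the same amount with or without effects, was 0.169 against 0.0535 simulated, a difference of 0.116, and the simulations called at most 0 genes the same way in both. Part of the overlap may still come from the shared WT libraries, which are too few to be divided. After GC correction 2257 genes went the same way and 846 opposite ways. YAP_KO and dKO, which share the WT libraries too, had 2314 genes called in the same direction and 51 in opposite ones, where independence would give 303 higher and 186 lower in both. Their covariance was 0.213 against 0.0535 simulated (correlation 0.70 against 0.49), and part of this overlap may come from the shared libraries as well. TAZ_KO and dKO had 1699 genes in the same direction and 1392 in opposite ones (1105 higher and 594 lower in both, where independence would give 766 and 817), with a covariance of 0.111 and a correlation of 0.15 against the same simulated values. The test of non-additivity, which compares dKO with the sum of the 2 single knockouts, called 10435 genes, 5505 with a positive and 4930 with a negative value. Its values followed GC content across genes (Spearman 0.75), and after GC correction 7690 genes were called. Of 10338 calls tested again, 5049 were called the same way and 913 the opposite way. It gave CTGF -0.48 ± 0.14 (adjusted p = 0.00574; -0.80 after GC correction), that is, lower in dKO than the sum. CYR61, at 0.31 ± 0.15, did not pass it (adjusted p = 0.0739), though it did with library quality weights (adjusted p = 0.00147) and without single libraries (adjusted p 0.0444 without TAZ_KO starved replicate 2 and 0.0186 without dKO starved replicate 1). The largest positive values were those of MIF, ATP5D and FASN (7.22, 6.94 and 6.90; 2.66, 3.55 and 3.0 corrected), and SP100, a nuclear body protein, stood at -4.22 (-3.95).

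In WT cells, 90 min of LPA raised a small set of YAP/TAZ targets and immediate-early genes. CTGF rose by 2.56 ± 0.10 log2 units (adjusted p = 1.5e-11) from 3.39 ± 0.440 to 24.8 ± 0.632 FPKM, and CYR61 by 1.44 ± 0.11 (adjusted p = 3.3e-07). EGR3 rose by 2.07 ± 0.10, FOSB by 1.86 ± 0.19, EGR1 by 0.94 ± 0.12 and FOSL1 by 0.99 ± 0.14, all transcription factors of the immediate-early response. DUSP5, a phosphatase that acts on ERK, rose by 1.1 ± 0.11, ATF3, a stress factor, by 0.81 ± 0.11, and TUFT1 by 0.73 ± 0.0863. limma called 11 genes, all higher (425 at an unadjusted p under 0.05), and 16 after GC correction. FHL2, an SRF target, rose by 0.57 ± 0.0941 (adjusted p = 0.0141), a call that depended on single libraries (adjusted p 0.0898 without WT LPA replicate 1, 0.118 without WT LPA replicate 2, 0.0898 without WT starved replicate 1, 0.0940 without WT starved replicate 2 and 0.0660 without WT starved replicate 3). The FOSL1 call was lost with a pseudocount of 0.1 (adjusted p = 0.447). With only the groups compared in the fit, the calls of FOSL1 (adjusted p = 0.178), TUFT1 (0.384), FHL2 (0.297) and FOSB (0.0501) were lost. ANKRD1 (0.43, adjusted p = 0.0571), FOS (0.72, adjusted p = 0.624) and MYC (-0.22, adjusted p = 1) did not pass the test, and ANKRD1 did after GC correction (adjusted p = 0.0492), with no FPKM filter (0.00942) and with library quality weights (0.0196). YAP1 (0.0315) and WWTR1 (0.17) did not pass it either.

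As sets in WT, conserved YAP/TAZ targets rose (2 of 17 tested were higher and 0 lower (6 and 0 adjusted over the list alone); camera adjusted p = 1.2e-15, adjusted p = 3.2e-06 with an estimated correlation), and so did immediate-early genes (6 of 42 tested were higher and 0 lower (14 and 0 adjusted over the list alone); camera adjusted p = 4.9e-30, adjusted p = 0.00478 with an estimated correlation). For SRF/MRTF cytoskeletal targets 2 of 25 tested were higher and 0 lower (3 and 0 adjusted over the list alone), camera adjusted p = 1.6e-06, lost at adjusted p = 0.256 with an estimated correlation. TGF-beta targets, in which CTGF was the called member, had a camera adjusted p of 0.0447 (1 of 14 tested was higher and 0 lower (1 and 0 adjusted over the list alone)), lost at adjusted p = 0.283 with an estimated correlation at 0.0523 after GC correction and at 0.105 with a pseudocount of 0.1. Replication-dependent histones were lower as a set with no member called. Of 18 tested, 0 were higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 1.1e-04, lost at adjusted p = 0.0788 with an estimated correlation.

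**Figure D3:**
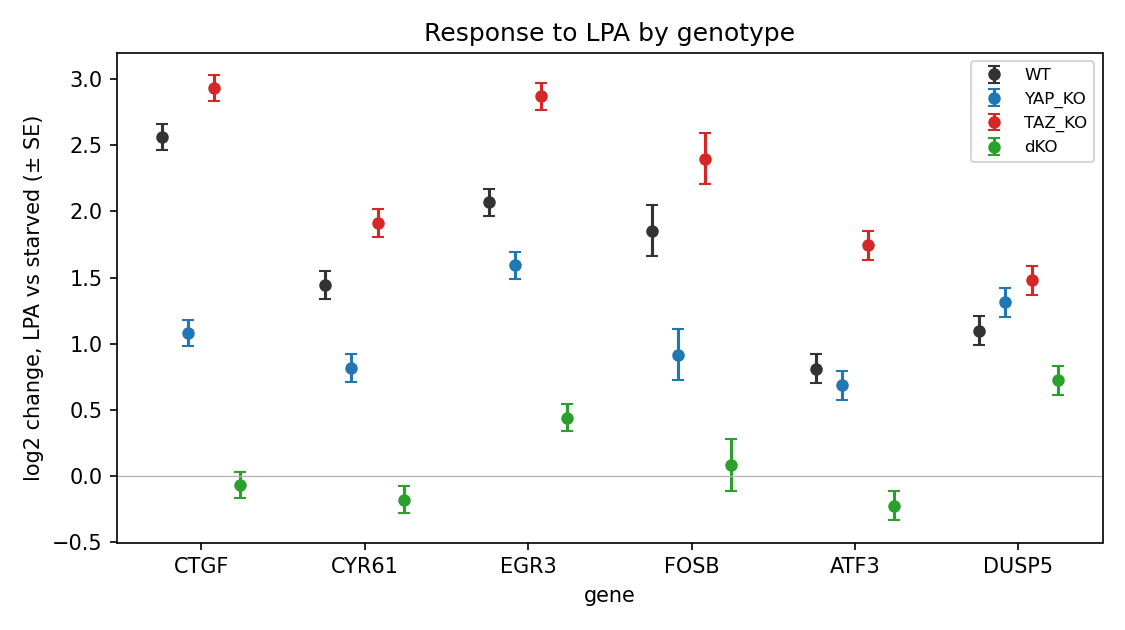
Change in log2(FPKM + 1) with LPA against starved cells (vertical axis, with the SE of the limma fit, 3 against 3 libraries) of CTGF, CYR61, EGR3, FOSB, ATF3 and DUSP5 in WT, YAP_KO, TAZ_KO and dKO. In dKO the changes of the first 5 lie between -0.23 and 0.44, and in WT between 0.81 and 2.56.

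In TAZ_KO, LPA raised CTGF, CYR61 and immediate-early genes. CTGF rose by 2.93 ± 0.10 (adjusted p = 1.4e-12), EGR3 by 2.87 ± 0.10, FOSB by 2.4 ± 0.19, CYR61 by 1.91 ± 0.11, ATF3 by 1.74 ± 0.11 and DUSP5 by 1.48 ± 0.11. EGR1 (1.28), TUFT1 (1.21) and FHL2 (1.00) rose too, while FOS (0.62, adjusted p = 0.925) and MYC (-0.30, adjusted p = 0.925) did not pass the test, and both did with library quality weights (adjusted p = 0.00130 and 1.3e-04). AMOTL2 rose by 1.24 (adjusted p = 0.0318), a call lost with a replicate block (adjusted p = 0.0661) and without single libraries (adjusted p 0.255 without TAZ_KO LPA replicate 1, 0.0867 without TAZ_KO LPA replicate 3, 0.224 without TAZ_KO starved replicate 1, 0.0837 without TAZ_KO starved replicate 2 and 0.106 without TAZ_KO starved replicate 3). Conserved YAP/TAZ targets (3 of 17 tested were higher and 0 lower (5 and 0 adjusted over the list alone); camera adjusted p = 8.7e-10, adjusted p = 8.2e-05 with an estimated correlation), immediate-early genes (12 of 42 tested were higher and 0 lower (24 and 0 adjusted over the list alone); camera adjusted p = 4.1e-50, adjusted p = 3.3e-04 with an estimated correlation) and SRF/MRTF targets (3 of 25 tested were higher and 0 lower (7 and 0 adjusted over the list alone); camera adjusted p = 3.8e-15, adjusted p = 0.0245 with an estimated correlation) rose as sets. limma called 24 genes, 23 higher and 1 lower. The count was 41 after GC correction, 15 without TAZ_KO LPA replicate 1, 14 without its replicate 3, 15 without TAZ_KO starved replicate 3 and 9 with only the groups compared in the fit, where ATF3 (adjusted p = 0.103), FHL2 (0.297), FOSB (0.103) and AMOTL2 (0.938) lost their calls. With GC correction in that fit 3 genes were called, and CTGF was not among them (adjusted p = 0.0958).

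In YAP_KO, CTGF rose with LPA by 1.08 ± 0.10 (adjusted p = 1.1e-05) from 1.38 ± 0.107 to 4.03 ± 0.258 FPKM and CYR61 by 0.81 ± 0.11 (adjusted p = 9.6e-04). EGR3 rose by 1.59 ± 0.10, DUSP5 by 1.31 ± 0.11 and TUFT1 by 0.91 ± 0.0863. ATF3 (0.68; adjusted p 0.0692 without YAP_KO LPA replicate 2), EGR1 (0.67; 0.0536 without YAP_KO starved replicate 2) and FOSB (0.91; 0.0931 without YAP_KO LPA replicate 1, 0.110 without YAP_KO LPA replicate 2, 0.0814 without YAP_KO starved replicate 1 and 0.0642 without YAP_KO starved replicate 2) were called higher. MYC was called lower (-0.84; adjusted p 0.196 without YAP_KO LPA replicate 1, 0.137 without YAP_KO LPA replicate 2, 0.0814 without YAP_KO starved replicate 1 and 0.0642 without YAP_KO starved replicate 2), with an adjusted p of 1 without the 8 libraries, and FOS did not pass the test (-0.26, adjusted p = 0.286). With only the groups compared in the fit, the calls of all genes named here were lost, at adjusted p = 0.115 for EGR3, 0.206 for CTGF and 0.216 for each of the others. After GC correction as well, that fit gave 0.0667 for EGR3 and 0.0906 for CTGF. The ATF3 call was also lost without the 8 libraries (adjusted p = 0.0617). For conserved YAP/TAZ targets 4 of 17 tested were higher and 2 lower (4 and 2 adjusted over the list alone), camera adjusted p = 0.544, direction up; median -0.0349, mean 0.0732, and for immediate-early genes 11 of 42 tested were higher and 4 lower (11 and 4 adjusted over the list alone), camera adjusted p = 0.209, 4.2e-08 after GC correction. With a shifted GC trend in 2 of the 3 LPA libraries, limma called 5153 genes (2428 higher, 2725 lower), and 954 after GC correction, when 683 of the 5109 calls that could be tested again were called in the same direction. It called 17 without the shifted libraries, 1 with only the groups compared in the fit, 20, 16 and 9454 without YAP_KO LPA replicates 1, 2 and 3, and 32, 25 and 1566 without starved replicates 1, 2 and 3.

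In dKO, the changes of CTGF, CYR61, EGR3, EGR1, FOSB and ATF3 with LPA did not pass the test, while that of DUSP5 did. CTGF went from 0.377 ± 0.161 to 0.306 ± 0.0295 FPKM (-0.0705 ± 0.10, adjusted p = 1) and CYR61 had a value of -0.18 ± 0.11 (adjusted p = 1). EGR3 (0.44 ± 0.10, adjusted p = 0.379), EGR1 (0.42), FOSB (0.0805), ATF3 (-0.23), FOS (0.13), MYC (-0.13) and ANKRD1 (-0.0186) did not pass it either. EGR3 was at 0.0768, 0.104 and 0.281 FPKM in the starved dKO libraries and at 0.532, 0.651 and 0.498 with LPA, without overlap. At such levels the adding of 1 shrinks the change, so the value of 0.44 does not show that EGR3 failed to respond. With library quality weights EGR3 (adjusted p = 0.0145) and EGR1 (adjusted p = 0.0213) were called higher and ATF3 (adjusted p = 0.0473) lower. limma called 3 genes: DUSP5 (0.72 ± 0.11, adjusted p = 0.0258) and SPRY2, an inhibitor of ERK signalling (0.51 ± 0.0827, adjusted p = 0.0463), higher, and an unnamed clone transcript lower. The DUSP5 call was lost after GC correction (adjusted p = 0.270), with only the groups compared in the fit (adjusted p = 0.344), with a replicate block (0.0539), without the 8 libraries of shifted GC trend (0.0540) and without single libraries (adjusted p 0.107 without dKO LPA replicate 1, 0.0513 without dKO LPA replicate 2, 0.225 without dKO LPA replicate 3, 0.212 without dKO starved replicate 2 and 0.185 without dKO starved replicate 3), and that of SPRY2 likewise (0.0806 after GC correction, 0.498 with only the groups compared, 0.16 with a replicate block, 0.0799 with a filter at FPKM 5, 0.0540 with a robust eBayes; 0.218 without dKO LPA replicate 1, 0.341 without dKO LPA replicate 2, 0.170 without dKO LPA replicate 3, 0.336 without dKO starved replicate 2 and 0.259 without dKO starved replicate 3). For conserved YAP/TAZ targets 0 of 17 tested were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.177, for immediate-early genes 2 of 42 tested were higher and 0 lower (4 and 1 adjusted over the list alone), camera adjusted p = 0.122, 0.0172 with a pseudocount of 0.1, direction up; median -0.01, mean -0.0168, and for SRF/MRTF targets 0 of 25 tested were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.00244, lost at adjusted p = 0.732 with an estimated correlation. The count of 3 genes was 1, 1 and 0 without dKO LPA replicates 1, 2 and 3 and 54, 0 and 0 without starved replicates 1, 2 and 3 (limma; 341, 279 and 282 at an unadjusted p under 0.05 where it was 0).

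Tested directly as an interaction, the LPA response in dKO was weaker than in WT for CTGF (-2.63 ± 0.14, adjusted p = 3.9e-09), FOSB (-1.77 ± 0.27, adjusted p = 0.0132), EGR3 (-1.63 ± 0.15, adjusted p = 1.3e-05), CYR61 (-1.62 ± 0.15, adjusted p = 1.3e-05) and ATF3 (-1.04 ± 0.16, adjusted p = 0.0132). The response of DUSP5 did not differ by the test (-0.38, adjusted p = 1). These were all 5 genes called by limma (352 at an unadjusted p under 0.05). Conserved YAP/TAZ targets had weaker responses as a set (0 of 17 tested were higher and 2 lower (0 and 4 adjusted over the list alone); camera adjusted p = 1.9e-16, adjusted p = 2.3e-06 with an estimated correlation), as had immediate-early genes (0 of 42 tested were higher and 3 lower (0 and 6 adjusted over the list alone); camera adjusted p = 3.5e-18, adjusted p = 0.0397 with an estimated correlation, lost at 0.0806 when this followed GC correction). TGF-beta targets, with CTGF the called member, had a camera adjusted p of 0.00136 (0 of 14 tested were higher and 1 lower (0 and 1 adjusted over the list alone); adjusted p = 0.0756 with an estimated correlation). The ATF3 call depended on single libraries (adjusted p 0.0614 without dKO LPA replicate 3, 0.0621 without dKO starved replicate 2 and 0.0528 without WT LPA replicate 2), as did that of FOSB (0.0581 without dKO LPA replicate 2, 0.0614 without dKO LPA replicate 3, 0.0621 without dKO starved replicate 2, 0.0682 without dKO starved replicate 3, 0.0504 without WT LPA replicate 3 and 0.0574 without WT starved replicate 1, and 0.0733 with a filter at FPKM 5), and that of EGR3 was lost with a pseudocount of 0.1 (adjusted p = 0.307). The count of 5 was 3 without dKO LPA replicate 3, 3 without dKO starved replicate 2 and 30 without dKO starved replicate 1.

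In YAP_KO the response of CTGF was weaker than in WT (-1.48 ± 0.14, adjusted p = 5.1e-05), the 1 gene called (2982 at an unadjusted p under 0.05). The call was lost after GC correction (-1.39, adjusted p = 0.0593), with quantile normalization (adjusted p = 0.123) and with a pseudocount of 0.1 (adjusted p = 0.233). CYR61 did not pass the test (-0.63, adjusted p = 0.264), except with library quality weights (adjusted p = 1.5e-05, 9646 genes called) and without YAP_KO LPA replicate 3 (adjusted p = 0.00201, 6667 genes called). These settings are alike, since the weights gave that replicate, the only YAP_KO LPA library without the GC shift, the lowest weight of all (0.0577). The count was 2 without WT LPA replicate 1, 4 without WT LPA replicate 2, 2 without WT starved replicate 2 and 2 without YAP_KO LPA replicate 1. In TAZ_KO limma called 0 genes (376 at an unadjusted p under 0.05), and 4 after GC correction. CTGF (0.37, adjusted p = 0.943) and CYR61 (0.47, adjusted p = 0.943) did not pass the test there, and CYR61 did with library quality weights (adjusted p = 0.0238). EGR3 (0.80, adjusted p = 0.0981) and ATF3 (0.93, adjusted p = 0.0768) passed it after GC correction (adjusted p = 0.0444 and 0.00488) and with library quality weights (0.0131 and 2.7e-04). ATF3 also did with TPM rescaling (0.0322) and trimmed-mean scaling (0.0149), and 1 gene was called without TAZ_KO LPA replicate 2 (ATF3, adjusted p = 0.0371) or without WT LPA replicate 1.

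With LPA present, CTGF was lower in dKO and YAP_KO than in WT, and CYR61 was lower in all 3 knockouts. CTGF was at -4.31 ± 0.10 in dKO against WT (adjusted p = 3.8e-16) and at -2.36 ± 0.10 in YAP_KO (adjusted p = 4.8e-12), while in TAZ_KO it did not pass the test (0.0593 ± 0.10, adjusted p = 0.603) and was higher after GC correction (0.38, adjusted p = 0.0421). CYR61 was at -3.06 in dKO, -1.28 in YAP_KO and -0.63 in TAZ_KO. Genes named for starved cells stood out here too: NEFL (5.15), CCND1 (3.75), SLC7A5 (-4.27) and KRT19 (-4.01) in dKO. In YAP_KO these were PUDP (3.62), FLRT2 (3.60) and SLC7A5 (-6.47), and in TAZ_KO FLRT2 (3.14; 2.72 corrected) and ATP5D (-6.09; -3.41 corrected). limma called 4492 genes in dKO (2204 higher, 2288 lower), 7415 in YAP_KO (3945 higher, 3470 lower) and 11075 in TAZ_KO (5202 higher, 5873 lower). After GC correction it called 7976 in TAZ_KO and 7156 in YAP_KO. In TAZ_KO, of 10968 calls tested again, 5327 were called the same way and 1120 the opposite way. In YAP_KO, of 7345 these were 5023 and 15. The YAP_KO count was 4199 without the shifted libraries, 4647 without YAP_KO LPA replicate 1 and 4841 without its replicate 2, and the dKO count was 7514 without the shifted libraries.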

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

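The tests of explanations in this part and the reading of the sample splits were written only after the results were seen, while the interactions and the test of non-additivity were set before. The results listed here are differences between genotypes in the response to LPA or departures from additivity, each past its own test. The LPA response of dKO differed from that of WT in 5 genes: CTGF (-2.63), FOSB (-1.77), EGR3 (-1.63), CYR61 (-1.62) and ATF3 (-1.04). That of YAP_KO differed in 1 gene, CTGF (-1.48). The starved level in dKO departed from the sum of the single knockouts in 10435 genes. After GC correction 5049 of 10338 calls tested again were called in the same direction and 913 in the opposite one. Among those named were CTGF (-0.48; -0.80 corrected), MIF (7.22; 2.66), ATP5D (6.94; 3.55), FASN (6.90; 3.0) and SP100 (-4.22; -3.95).

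The first pattern is the number of genes called in TAZ_KO against WT, with GC-rich genes lower. Whether the GC trend was the whole cause is not decided: after GC correction 5934 calls kept their direction and 1589 turned. The first principal component of the corrected levels still held 44.2% of the variance. It set the same 8 libraries apart: YAP_KO LPA replicates 1 and 2 scored 0.20 and 0.13, and replicate 3 scored -0.12. The kept calls can therefore hold differences between libraries that a curve on GC content does not remove. Loss of TAZ in any background as the cause of the trend is argued against by dKO, where TAZ is also deleted and the correlation of log2 change with GC content across genes was 0.0231. A difference between libraries may give such a trend within a group, since the 3 YAP_KO LPA libraries spanned 2.59 log2 units in their GC-rich genes. In TAZ_KO itself, where 6 of 6 libraries were shifted, library preparation and genotype cannot be told apart, because no TAZ_KO library without the shift exists to compare.

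The second pattern is the weaker LPA response of CTGF, CYR61, EGR3, FOSB and ATF3 in dKO. Less LPA receptor mRNA in sum is argued against: LPAR1 to LPAR6 summed to 13.6 ± 0.314 FPKM in starved dKO and 12.4 ± 0.630 in WT (SD, n = 3), or 109%. The sum hides opposite changes from WT to dKO. LPAR2 fell from 4.55 to 2.09 FPKM and LPAR3 from 1.72 to 0.548, while LPAR1 rose from 6.08 to 9.39 and LPAR6 from 0.0107 to 1.52. Loss of a particular receptor therefore stays open. A common reduction of all responses stays open. The 11 WT-called genes had a spread of 78.2 around it (1000 simulations: 95th percentile 18.0), but adding 1 shrinks changes at low FPKM more. A higher starved level, which leaves less room to rise, held for 1 of the 5 genes and stays open for that gene. What else lies behind the weaker responses stays open, and the cell lines differ in other ways, such as the chromosome segments.

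Of the 100 splits of the samples drawn for the test of non-additivity, 1 gave as many calls as the 10435, the real one (highest other 8632). These splits mix genotypes that differ and do not leave the effects additive, so they do not test non-additivity against chance. For the number of genes called in the interactions, which says nothing of the size of a single gene's change, chance was not excluded: 10 of 100 splits gave as many genes as the 5 of dKO (highest other 8) and 54 as many as the 1 of YAP_KO (highest other 67). For TAZ_KO, where 0 genes were called, all 100 splits give as many by necessity (highest other 5), so the splits say nothing there. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count and the highest other were 3653 and 2 for YAP_KO against WT starved, 11950 and 1 for TAZ_KO against WT starved, 4205 and 2 for dKO against WT starved, 11 and 6 for LPA in WT, 5153 and 5536 for LPA in YAP_KO, 24 and 2179 for LPA in TAZ_KO, 3 and 2 for LPA in dKO, 7415 and 5755 for YAP_KO against WT with LPA, 11075 and 2 for TAZ_KO against WT with LPA, 4492 and 1 for dKO against WT with LPA, 11649 and 2 for YAP_KO against TAZ_KO, 1700 and 2 for dKO against YAP_KO and 11828 and 1 for dKO against TAZ_KO. The real split was among 2 as large for LPA in YAP_KO, 3 for LPA in TAZ_KO and 1 for the others. The highest other split called 2179 genes against the real 24 for LPA in TAZ_KO, and 67 against 1 for the YAP_KO interaction. This points to a structure of the samples.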

How the results depend on the processing

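Alternatives involving GC content, the 8 shifted libraries, the chromosome segments and the deleted genes were chosen only after the data were seen, and so was the gene-by-gene estimator of the quality weights, because the default one gave weights from 0.00670 to 697283. The gene-by-gene weights ran from 0.0577 for YAP_KO LPA replicate 3, which was not shifted, to 11.1 for TAZ_KO LPA replicate 3, which was. YAP_KO LPA replicate 2, also shifted, had 5.45. Calls gained with these weights can thus rest on libraries of shifted GC trend. The planned fit on raw counts was not run, since the files hold none. Counts and deleted-gene levels stayed within 1.5 times, or on their side of the test, in 199 cases and moved in 80; with single libraries left out these were 179 and 27, plus 1 that came to pass the test. For 230 results of named genes and 60 of lists, 3383 cases kept their direction and side of the threshold, 143 lost and 29 gained a call, and 10 reversed; with single libraries left out 1426 kept it, 57 lost and 5 gained it. With library quality weights the count was 7784 for YAP_KO against WT starved, 7670 for dKO against WT starved, 23 for LPA in WT, 12005 for LPA in YAP_KO, 2349 for LPA in TAZ_KO, 282 for LPA in dKO, 9646 for the YAP_KO interaction, 129 for the TAZ_KO interaction, 47 for the dKO interaction, 11804 for YAP_KO against WT with LPA, 7819 for dKO against WT with LPA, 5577 for dKO against YAP_KO and 3882 for the YAP_KO and TAZ_KO overlap. With only the groups compared in the fit the count was 7153 for YAP_KO against WT starved, 1 for LPA in YAP_KO, 9 for LPA in TAZ_KO, 5 for LPA in dKO, 1461 for YAP_KO against WT with LPA, 6754 for dKO against WT with LPA, 2822 for dKO against YAP_KO and 3217 for the YAP_KO and TAZ_KO overlap. With a fold of at least 1.5 required the count was 1764 for YAP_KO against WT starved, 2189 for dKO against WT starved, 2415 for LPA in YAP_KO, 4405 for YAP_KO against WT with LPA, 7317 for TAZ_KO against WT with LPA, 2449 for dKO against WT with LPA and 870 for dKO against YAP_KO. With GC correction and only the groups compared the count was 7468 for YAP_KO against WT starved, 7451 for TAZ_KO against WT starved, 6848 for dKO against WT starved, 0 for LPA in YAP_KO, 3 for LPA in TAZ_KO, 5 for LPA in dKO, 8 for the dKO interaction, 4176 for YAP_KO against WT with LPA, 5474 for TAZ_KO against WT with LPA, 7533 for dKO against WT with LPA, 4132 for dKO against YAP_KO and 2806 for the YAP_KO and TAZ_KO overlap. Without the 8 libraries of shifted GC trend the count was 6822 for YAP_KO against WT starved, 7196 for dKO against WT starved, 17 for LPA in YAP_KO, 6 for the YAP_KO interaction, 4199 for YAP_KO against WT with LPA, 7514 for dKO against WT with LPA and 4179 for dKO against YAP_KO. With GC correction and only genes of GC content under 0.48 the count was 3969 for TAZ_KO against WT starved, 4 for LPA in WT, 225 for LPA in YAP_KO, 12 for LPA in TAZ_KO, 0 for the YAP_KO interaction, 1 for the TAZ_KO interaction, 1 for the dKO interaction, 3917 for YAP_KO against WT with LPA, 3512 for TAZ_KO against WT with LPA, 4338 for YAP_KO against TAZ_KO, 4765 for dKO against TAZ_KO and 3696 for non-additivity. With no FPKM filter the count was 38 for LPA in WT, 1967 for LPA in YAP_KO, 7 for LPA in dKO, 4 for the YAP_KO interaction, 2 for the TAZ_KO interaction and 11 for the dKO interaction. With GC correction the count was 954 for LPA in YAP_KO, 41 for LPA in TAZ_KO, 1 for LPA in dKO, 0 for the YAP_KO interaction, 4 for the TAZ_KO interaction and 3046 for dKO against YAP_KO. With a filter at FPKM 5 the count was 14 for LPA in TAZ_KO and 0 for LPA in dKO. With a replicate block the count was 0 for LPA in dKO. With a pseudocount of 0.1 the count was 0 for the YAP_KO interaction and 1 for the TAZ_KO interaction. With quantile normalization the count was 0 for the YAP_KO interaction and 1 for the TAZ_KO interaction. With TPM rescaling the count was 3 for the TAZ_KO interaction. With trimmed-mean scaling the count was 3 for the TAZ_KO interaction. Where limma called 0 genes, the number at an unadjusted p under 0.05 was 2559 for LPA in YAP_KO with GC correction and only the groups compared, 822 for the YAP_KO interaction with GC correction and only genes of GC content under 0.48, 1808 for the YAP_KO interaction with GC correction, 179 for LPA in dKO with a filter at FPKM 5, 382 for LPA in dKO with a replicate block, 2537 for the YAP_KO interaction with a pseudocount of 0.1 and 3596 for the YAP_KO interaction with quantile normalization. Directions reversed for CTGF, TAZ_KO vs WT, starved (0.41 with quantile normalization, 0.0299 with GC correction); EGR1, TAZ_KO vs WT, starved (0.11 with quantile normalization, 0.19 with GC correction); CYR61, YAP_KO vs TAZ_KO, starved (-0.28 with quantile normalization); WWTR1, dKO vs TAZ_KO, starved (0.13 with GC correction). Leaving out single libraries moved the counts to 2658 to 2842 for YAP_KO against WT starved, 11164 to 11854 for TAZ_KO against WT starved, 3264 to 3484 for dKO against WT starved, 10 to 15 for LPA in WT, 16 to 9454 for LPA in YAP_KO, 14 to 29 for LPA in TAZ_KO, 0 to 54 for LPA in dKO, 4647 to 9988 for YAP_KO against WT with LPA, 9497 to 11464 for TAZ_KO against WT with LPA, 3569 to 3935 for dKO against WT with LPA, 10768 to 11530 for YAP_KO against TAZ_KO, 1208 to 1491 for dKO against YAP_KO, 10949 to 11676 for dKO against TAZ_KO, 1 to 6667 for the YAP_KO interaction, 0 to 1 for the TAZ_KO interaction, 3 to 30 for the dKO interaction, 9539 to 10584 for non-additivity and 1175 to 1756 for the YAP_KO and TAZ_KO overlap, and WWTR1 in YAP_KO to 106 to 112% of WT. Requiring a fold can only lower a count. The setting with only genes of low GC content changes the correction and the genes tested at once, and the causes of the other differences were not tested. The depth behind each FPKM is known only roughly, which limits genes near an FPKM of 1 most.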

Other observations

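The tests of explanations in this part were chosen only after the results were seen. From YAP_KO to dKO in starved cells, more gene groups moved than the report describes. Extracellular matrix genes fell, with SPARC at -2.57, CD44 at -1.86 and LAMA4 at -1.79. Of 39 tested, 1 was higher and 9 lower (1 and 12 adjusted over the list alone), with camera adjusted p = 0.00337, lost at adjusted p = 0.373 with an estimated correlation. Interferon-stimulated genes fell, with IFITM3 at -2.19 and BST2 at -1.39. Of 24 tested, 0 were higher and 7 lower (0 and 7 adjusted over the list alone), with camera adjusted p = 0.0209, lost at adjusted p = 0.230 with an estimated correlation. With quantile normalization the set had an adjusted p of 0.0505. The BST2 call depended on single libraries (adjusted p 0.0816 without dKO starved replicate 3, 0.0538 without YAP_KO starved replicate 1, 0.0593 without YAP_KO starved replicate 2 and 0.0534 without YAP_KO starved replicate 3). G1/S and DNA replication genes rose, with RRM2, a ribonucleotide reductase subunit, at 0.54 against RFC4, of chromosome 3, at -1.04. Of 41 tested, 4 were higher and 1 lower (4 and 1 adjusted over the list alone), with camera adjusted p = 0.00337, lost at adjusted p = 0.280 with an estimated correlation. Among LPA receptors, named here after their values were seen, LPAR1 was higher in starved dKO than in WT (0.55, adjusted p = 1.6e-05). LPAR2 (-0.85, adjusted p = 0.0133, but 0.0555 without dKO starved replicate 1 and 0.0539 with a pseudocount of 0.1) and LPAR3 (-0.82, adjusted p = 1.2e-05) were lower.

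Some genes were present in certain cell lines and near 0 in others. With group means under 0.1 FPKM counted as off and of at least 1 as on, limits chosen after seeing the data, 11 genes were off in WT and TAZ_KO and on in YAP_KO and dKO: BEND5, COL23A1, HYLS1, NEDD4, PUDP, RFX7, SOX11, STS, TEX9, TNK1 and ZNF502. Required of every library, the same limits gave 6 of them (HYLS1, NEDD4, RFX7, SOX11, STS and ZNF502). NEDD4, a ubiquitin ligase, stood at 0 ± 0 FPKM in starved WT and 6.46 ± 0.831 in starved YAP_KO. B3GALNT1 and TRIM59, both on chromosome 3, were off in every dKO library and on in every other one. KPNA4, which lies between them, stood at 38.6 ± 3.27 FPKM in dKO (n = 6). KCNK2 was off in every WT library and on in every other. By group means the same limits gave 43 genes off in TAZ_KO alone and 6 off in dKO alone, of which 0 and 2 held in every library, so group means are a loose rule in the line with the shifted GC trend.

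The third pattern is that some genes whose levels differ between the cell lines lie close to each other. Among the 11 genes off in WT and TAZ_KO, 4 pairs lay within 1 Mb, against at most 2 in 1000 random draws (1 pair by the stricter of 2 rules tried, reached in 16 draws), and 11 neighbouring bins of chromosome 3 in dKO and 4 of chromosome 5 in YAP_KO had a median below -0.3, against at most 1 in 200 shuffles. Gain or loss of chromosome segments, or silencing over a stretch, in the cells from which a line was grown may account for all 3, as a hypothesis from the same data. Loss of YAP as a switch for the genes off in WT and TAZ_KO remains open, since they were on in both, that is 2, genotypes without YAP, and a difference between parent cells cannot be told apart from it here. DNA copy number was not analysed here, and the bins cannot show whether DNA or its reading changed.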
